A study of Mus musculus with 4 samples.

How the data were processed

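The samples were seminal vesicles harvested from 4 wild-type (Nkx3.1 +/+) C57Bl/6J mice of 15 months and snap frozen. Per the labels' protocols, RNA was taken up in Trizol and cleaned on RNeasy columns, labelled with biotin and hybridised to Affymetrix Mu74AV2 GeneChips. The deposited values are log2 expression values per probe set, made with RMA per the submitters' processing notes. RMA corrects background, sets arrays to a common distribution and summarises the probes of a set by a robust fit. Its version, and which arrays were normalized together, are not given in the sources used here. That the scale is log2 was read from the values, which ran from 1.47 to 13.2 on the 4 arrays, and no further transformation was applied. RMA shrinks differences of dim probe sets and removes shifts that all probe sets of an array share, so a change of most genes at once would not appear.

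The table held 12488 probe sets. The 66 Affymetrix control probe sets were kept out of tests, which left 12422. Gene names came from the platform's annotation table and were matched by gene ID to a RefSeq table of assembly GRCm38.p6, which was used for names and neighbours only. A single gene was given for 10833 probe sets, several genes for 396 and none for 1193. Of the 10833, 10817 matched by gene ID and 16 did not. Probe sets without a single gene entered the variance test but were given no name. The 8251 genes included 2073 with more than 1 probe set. A gene was then represented by its probe set of highest mean value, except that a called probe set is reported as such, and levels of different probe sets were not set against each other. An older array's probe sets can read related transcripts, above all within the immunoglobulin families.

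The mice were numbered 1 to 4 in the order of the series, which only names them. The labels give 1 group, so 3 results were defined within it before the data were examined, together with 32 gene lists, the rule for named genes and the alternatives. For the first result, a probe set was called variable when its variance over the 4 arrays (3 residual degrees of freedom) exceeded the prior variance of limma's model by an upper-tail F test. The prior was fitted robustly with mean signal as trend and had 8.06 degrees of freedom, and p-values were adjusted by Benjamini-Hochberg over 12422 probe sets at 0.05. For the second, a probe set was above the background range when it exceeded each array's 90th percentile of the other-organ probe sets on all 4 arrays, and a gene was when any of its probe sets was. For the last, and for each list with at least 5 genes whose mean exceeded the mean limit of 6.12, the mean deviation of its genes from their own 4-mouse means was computed per array. The SD of these 4 values was set against 10000 random lists of the same size, drawn from 2656 genes and matched on signal in 10 bins, one-sided, with Benjamini-Hochberg adjustment over 18 lists. Control probe sets for Gapdh and beta-actin gave the 3' minus 5' difference of each array.

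The rule for named genes took every measured gene of the title list, the first 3 measured genes of each other list, up to 3 called genes per list, up to 20 called single-gene probe sets of largest SD with mean above the mean limit, and for each array the 3 such probe sets furthest above and below the other mice. It named 107 probe sets. Genes named outside it are said to be so. Alternatives covered other scalings of the arrays, leaving out each mouse, other prior fits, filters on dim probe sets, other background limits, and other ways to combine probe sets and list members. Both tests were checked on simulated data with the prior variance and signal of these arrays. With no probe set changed the variance test made 0 calls among 12422. The list test called 100% of 30 simulated lists shifted by 0.3 on 1 array and 1 of 30 unshifted lists. Simulated values were drawn from the fitted model and were independent between genes. These checks therefore did not test the model itself or the effect of correlated genes. Work was done in R 4.3.3 with limma 3.58.1, and figures were drawn in Python 3.11.15 with matplotlib 3.10.9.

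No array was left out. The number of arrays, 4, limits the precision of every value. P-values set a probe set's variance against the prior fitted over all probe sets, or a group of genes against random draws of genes. They describe these 4 samples and do not extend to other mice.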

Results

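Total RNA from the seminal vesicles of 4 wild-type (Nkx3.1 +/+) C57Bl/6J mice of 15 months was hybridised to Affymetrix Mu74AV2 GeneChips, 1 array per mouse. The seminal vesicle is the male accessory gland that secretes most of the fluid of the ejaculate, and the series title places the arrays in a study of prostate differentiation that involves the histone methyltransferase G9a (gene Ehmt2) and the Y-linked gene UTY. All 4 arrays belonged to a single group, so no comparison between genotypes, ages or tissues was made. The arrays address which genes gave signal in the wild-type gland and which differed between its 4 mice. Values are log2 expression values per probe set, and the number of arrays limits their precision. The labels give each array its own animal number but do not state litter, cage or hybridisation batch.

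The 4 arrays resembled each other closely. Array medians over 12422 probe sets lay between 4.95 and 4.98. Pearson's r across probe sets, which are not independent replicates, ran from 0.992 to 0.994 for the 6 pairs of arrays, and 12 to 41 probe sets of a pair differed by more than 1 log2 unit. The 3' minus 5' difference of the Gapdh control was -0.14 ± 0.02 (SD, n = 4 mice), and that of the beta-actin control was 0.97 ± 0.11 (SD, n = 4), with 1.08 in mouse 1, 0.82 in mouse 2, 1.02 in mouse 3 and 0.98 in mouse 4. The arrays' files were not copies of one another, since at most 1 of 12422 probe sets had exactly the same value, compared without rounding, on both arrays of a pair.

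The first question was which genes gave signal in the gland. Secretory proteins of the seminal vesicle did so in every mouse. Svs2, which encodes a main structural protein of the copulatory plug, had a value of 12.53 ± 0.10 (SD, n = 4), Svs4 had 12.99 ± 0.03 and Svs5 had 13.09 ± 0.06. Of 15 measured genes of the seminal vesicle secretion list, 10 lay above the background range on all 4 arrays. Among members picked after their values were seen, Svs6 had 10.68 ± 0.21, Sva 12.69 ± 0.05 and Ceacam10 12.10 ± 0.02 (SD, n = 4 each), while Spink1, a trypsin inhibitor, did not exceed the range at 3.69 ± 0.20. The background range was set on each array by the 90th percentile of 130 probe sets for 103 genes of other organs, which was 6.18, 6.02, 6.05 and 6.22 in mice 1 to 4. By this limit 2917 of 12422 probe sets, or 23.5%, and 2366 of 8251 genes, or 28.7%, were above the range. The limit is strict and its choice moved the count by more than 1.5 times, to 5644 probe sets with the 75th percentile and 5834 with each array's median.

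Of the prostate list, 3 of 12 measured genes were above the background range. Hoxb13, a posterior homeobox gene, had 6.16 ± 0.09 (SD, n = 4) and passed the limit narrowly, and the other 2, Psca at 6.52 ± 0.20 and Pigr at 6.66 ± 0.17, were named after their values were seen. At the 95th percentile of the other-organ probe sets 0 of these genes passed. Msmb, a secreted prostate protein, had 3.39 ± 0.24 and did not pass. Pbsn, the androgen-dependent prostate secretory gene probasin, averaged 4.06 ± 1.68 and exceeded the limit in mouse 1 alone, at 6.57.

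Of the genes in the series title and their relatives, Ehmt2 lay above the background range at 7.29 ± 0.13 (SD, n = 4). Uty had 2.72 ± 0.07, its X-linked homologue Kdm6a had 5.39 ± 0.13, and Ezh2, the H3K27 methyltransferase, had 4.12 ± 0.13, none of them above the range. Ehmt1 and Kdm6b were not analysed here. The Y-linked genes Kdm5d (3.91 ± 0.06) and Eif2s3y (4.27 ± 0.09) also stayed under the limit although the tissue is male, so a value under it was no evidence that a gene was silent. The X-linked homologue of the latter, Eif2s3x, had 8.35 ± 0.13 and Ddx3x had 8.08 ± 0.18, both named after their values were seen, and they accounted for the 2 of 7 genes above the range in that list.

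Markers of luminal epithelium and smooth muscle gave signal, and those of basal epithelium largely did not. In the luminal list 13 of 20 measured genes were above the background range, among them the keratin genes Krt8 (8.50 ± 0.09, SD, n = 4), Krt18 (8.17 ± 0.19) and Krt19 (8.08 ± 0.38). In the smooth muscle list 12 of 17 were, including the contractile genes Acta2 (8.81 ± 0.25), Myh11 (9.60 ± 0.20) and Actg2 (10.17 ± 0.28). In the basal list 1 of 11 was, and Krt5 (4.80 ± 0.16), Krt14 (4.42 ± 0.13) and Trp63 (5.04 ± 0.04) were not. The fibroblast and matrix list had 14 of 28 above, with Col1a1 at 6.93 ± 0.14, Col1a2 at 7.35 ± 0.12 and Col3a1 at 5.82 ± 0.06, the last not above. Endothelial genes were above in 2 of 13 cases, with Pecam1 at 7.22 ± 0.19, while Cdh5 (4.05 ± 0.13) and Tek (2.78 ± 0.15) were not above.

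Functional lists were counted in the same way, without a test between lists. Of 31 measured genes of the secretory pathway and unfolded protein response, 24 were above the background range, among them the endoplasmic reticulum chaperones Hspa5 (9.73 ± 0.02, SD, n = 4) and Hsp90b1 (9.16 ± 0.11), whereas Calr had 3.15 ± 0.10. Mitochondrial respiration had 15 of 24 genes above, polyamine, fructose and prostaglandin synthesis 10 of 17, and antioxidant enzymes 13 of 27. Among those above were Srm, the spermidine synthase gene, at 8.09 ± 0.11, Gpx1 at 6.92 ± 0.09 and Gpx3 at 8.10 ± 0.13. Cycs (3.65 ± 0.07), Cox4i1 (5.19 ± 0.12), Cox5a (3.64 ± 0.19), Odc1 (5.74 ± 0.02) and Gpx2 (4.63 ± 0.10), also named by the rule, were not above. Of androgen signalling genes 5 of 18 were above, including the androgen-induced Fkbp5 at 8.05 ± 0.09 and its relative Fkbp4 at 9.04 ± 0.10, while Hsd17b4 (5.98 ± 0.11) was not. Urogenital patterning factors were above in 6 of 33 cases, and Hoxa10 (2.47 ± 0.07), Hoxa11 (4.25 ± 0.17) and Hoxa13 (5.05 ± 0.04) were not among them. Cell cycle genes were above in 4 of 25 cases, with the proliferation marker Mki67 at 4.37 ± 0.18 and Top2a at 3.86 ± 0.13. Senescence and ageing genes were above in 5 of 13, with Cdkn1a at 6.76 ± 0.05 and Cdkn2a at 5.45 ± 0.18.

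Immune lists were above the background range in 10 of 24 genes for macrophages and dendritic cells, 4 of 13 for B and plasma cells, 3 of 16 for T and NK cells, 4 of 21 for the interferon response, 1 of 21 for neutrophils and acute inflammation and 1 of 9 for mast cells. The macrophage markers Cd68 (4.83 ± 0.12, SD, n = 4), Adgre1 (4.88 ± 0.16) and Csf1r (5.39 ± 0.12) were not above it. Lists of tissue next to the gland or of blood were above in 2 of 19 genes for vas deferens, epididymis and testis, 2 of 4 for urothelium and bladder, 4 of 17 for adipocytes, 4 of 17 for skeletal muscle, 1 of 16 for nerve and Schwann cells and 2 of 7 for erythrocytes. Acta1, the skeletal muscle actin gene, had 9.51 ± 0.23, Upk2, a urothelial plaque gene, had 6.67 ± 0.15 and Hba-a1, an alpha globin gene, had 8.12 ± 0.39. The other genes named by the rule in the same lists were not above the range. In skeletal muscle these were Ckm (5.04 ± 0.14) and Myh4 (5.05 ± 0.08), and in urothelium Krt20 (3.85 ± 0.22) and Sprr1a (5.17 ± 0.18). In erythrocytes they were Hbb-b2 (4.61 ± 0.50) and Alas2 (5.51 ± 0.21). Immediate early genes were above in 9 of 27 cases and heat shock and hypoxia genes in 9 of 19. The other-organ list that set the limit had 8 of 103.

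**Figure D1:**
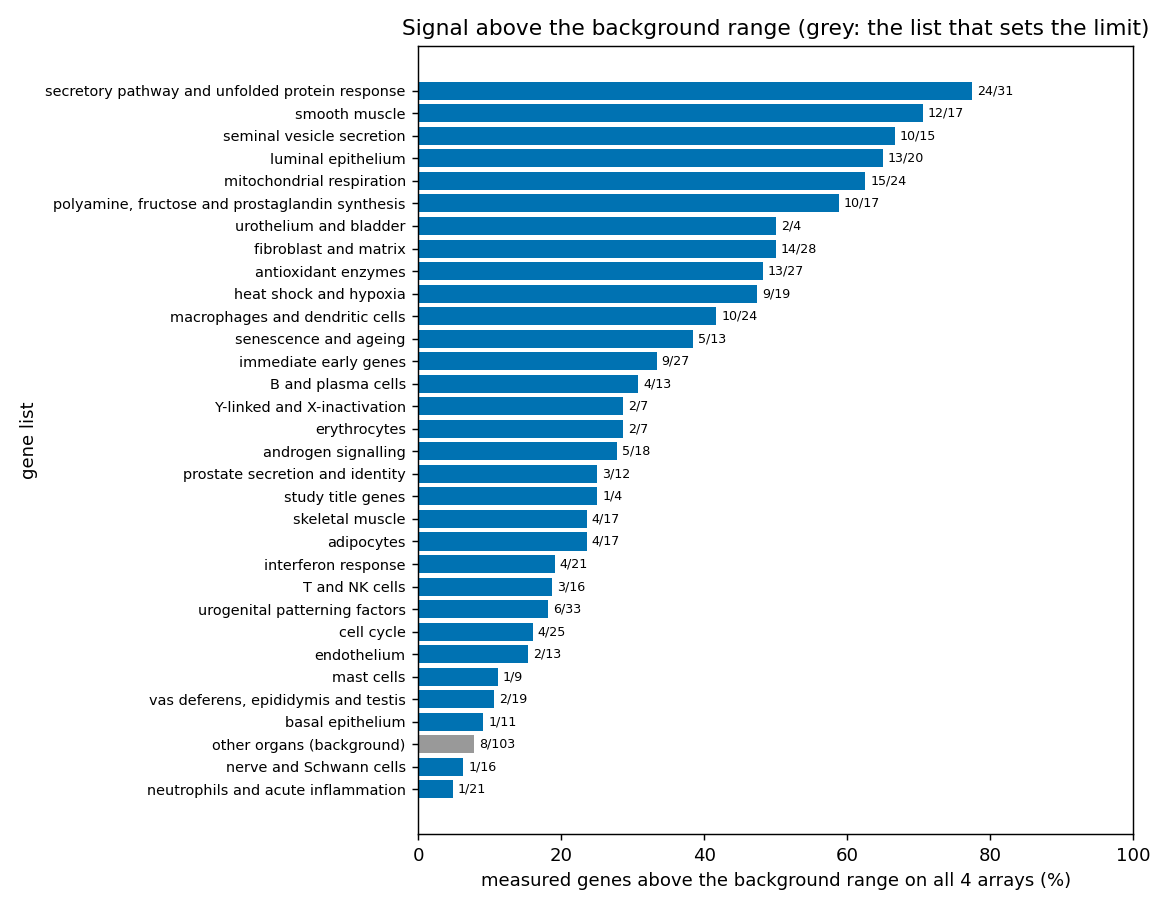
Horizontal bars give, for each of 32 gene lists, the percentage of measured genes above the background range on all 4 arrays, with the counts at the bar ends. The secretory pathway list reached 77.4% (24 of 31), seminal vesicle secretion 66.7% (10 of 15), and the other-organ list that sets the limit 7.77% (8 of 103).

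The second question was which genes differed between the 4 mice by more than the general spread of the arrays. The probasin gene Pbsn was called, with 6.57 in mouse 1 against 3.02, 3.18 and 3.47 in mice 2, 3 and 4, an SD of 1.68 (adjusted p = 0.0015, limma's variance model). The values of mice 2 to 4 were under the background limit, so the size of this difference is uncertain. Immunoglobulin genes formed the largest named group, with 10 of the 20 called single-gene probe sets counting the J chain. Ighm, the IgM heavy chain gene, had 8.51, 9.14 and 8.67 in mice 1 to 3 and 6.57 in mouse 4 (SD 1.13, adjusted p = 0.00733, limma), and Igha, the IgA heavy chain gene, had 7.0, 7.96, 7.98 and 6.34 (SD 0.80, adjusted p = 0.0242, limma). Jchain, which links IgA and IgM into polymers, had 5.86, 6.55, 6.74 and 5.20 (SD 0.70, adjusted p = 0.0332, limma). The Jchain call ended with arrays shifted to the same median (SD 0.70, adjusted p = 0.0593, limma) and without a trend (adjusted p = 0.0548, limma). The calls of Jchain and Igha ended with a non-robust prior fit (adjusted p = 0.0805 and 0.0539, limma). They also ended with the mean of all probe sets of a gene, at SDs of 0.70 and 0.40 (adjusted p = 0.0992 and 0.494, limma).

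The other called immunoglobulin genes named by the rule were likewise lowest in mouse 4. Igkv6-23 had 8.02 there against 9.57, 10.13 and 10.40, Igkv6-14 had 4.96 against 6.08, 6.54 and 6.90, Ighv1-54 had 5.35 against 6.30, 7.01 and 6.79, and a further kappa variable gene had 5.19 against 6.35, 6.83 and 6.60. The call of Ighv1-54 ended without mouse 2 (adjusted p = 0.0541, limma). That of the further kappa gene ended with arrays shifted to the same median (adjusted p = 0.0508, limma). Both ended with a non-robust prior fit (adjusted p = 0.0702 and 0.0706, limma). In the B and plasma cell list 3 of 13 genes were called, and 3 when adjusted over the list alone, whereas the B cell surface genes Cd79a (6.01 ± 0.16, SD, n = 4), Cd79b (4.98 ± 0.10) and Ms4a1 (6.12 ± 0.08) were not. Ighm is read by 16 probe sets of the array, and the mean over them had an SD of 0.14 (adjusted p = 0.991, limma). A second Ighm probe set was also called, at 6.89, 7.70, 7.87 and 6.33 in mice 1 to 4 (SD 0.72, adjusted p = 0.0326, limma). Most of the others were under the background limit on every array, and some of these were highest in mouse 4. Without mouse 4, none of Ighm (by its brightest probe set), Igha, Jchain, Igkv6-23, Igkv6-14, Ighv1-54 and that kappa variable gene was called. Ighm then had an SD of 0.33 (adjusted p = 0.86, limma), while Igha kept 0.56 (adjusted p = 0.255, limma) and Jchain 0.47 (adjusted p = 0.378, limma). The B and plasma cell list had too few genes above the limit for the main list test on 4 mice. With dim genes kept it was called on all 4 mice (SD 0.214 over 13 genes, permutation test, adjusted p = 7.5e-04), in a setting that called 15 of 30 lists. Leaving out a mouse brought further genes over the limit. The list was then called without mouse 4 (SD 0.303 over 6 genes, permutation test, adjusted p = 9.5e-04) and without mouse 1 (SD 0.576 over 6 genes, permutation test, adjusted p = 9.5e-04). These 2 calls are no test of the list on all 4 mice.

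Among the called genes outside the immunoglobulins, Rmdn3, a mitochondrial outer membrane protein gene, had 6.24 in mouse 1 against 8.44, 7.95 and 8.35 (SD 1.03, adjusted p = 0.00874, limma). Fcgbp, which encodes a mucin-like IgG Fc binding protein, had 7.88 in mouse 1 against 6.27, 6.08 and 5.94 (SD 0.90, adjusted p = 0.0147, limma), and its brighter probe set was not called, at 9.32, 8.75, 8.73 and 8.88. Tubb2a, a beta tubulin gene, had 6.14, 7.79, 7.07 and 8.18 (SD 0.89, adjusted p = 0.0153, limma). Arcn1, the delta subunit of the COPI coat, had 7.98 and 8.01 in mice 1 and 3 and 6.74 and 6.85 in mice 2 and 4 (SD 0.69, adjusted p = 0.0413, limma). This call was marginal: at SDs of 0.66 to 0.73 it ended with either rescaling of the arrays, without mouse 2, without mouse 4, with a non-robust prior fit and without a trend (adjusted p from 0.0504 to 0.0915, limma). Gas5, outside the rule as its mean of 5.95 was under the limit, had 6.85, 5.08, 7.37 and 4.49 (SD 1.38, adjusted p = 0.00296, limma). Further probe sets of Tubb2a, Arcn1 and Gas5 were not called. Gas5, Rmdn3, Tubb2a, Arcn1 and, outside the rule, Rell1, Oit1 and Kif5b had mice 1 and 3 on one side of mice 2 and 4. Pbsn, Fcgbp and Snhg6, the last outside the rule, did not, and 33.2% of all genes had this order. Without mouse 1 neither Pbsn (SD 0.23, adjusted p = 0.916, limma) nor Rmdn3 (SD 0.26), Fcgbp (SD 0.17) or Tubb2a (SD 0.56) was called.

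**Figure D2:**
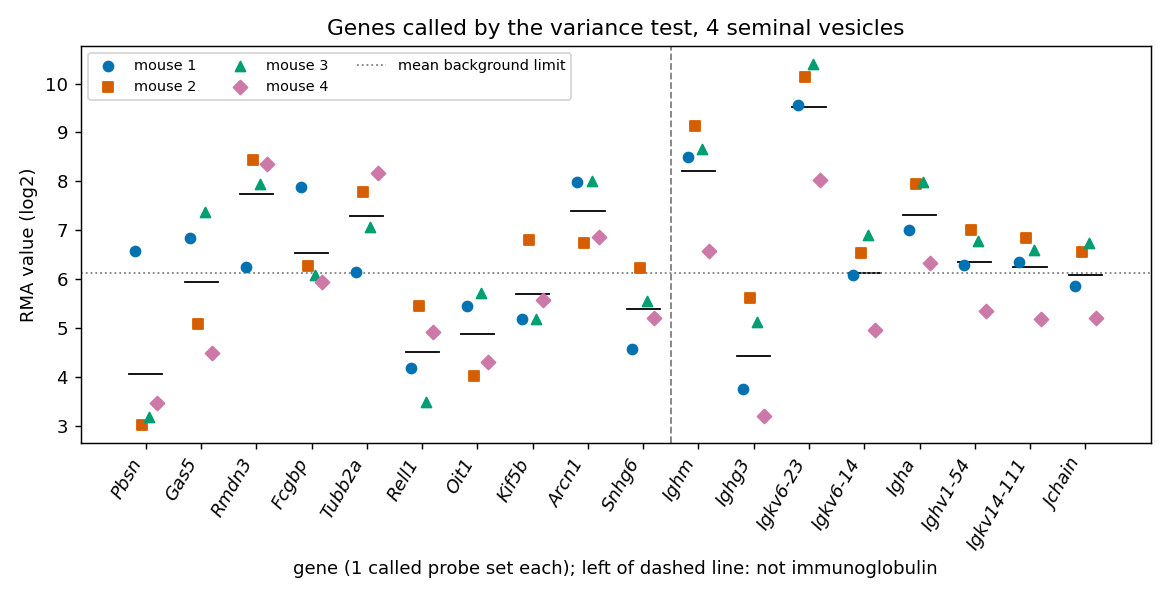
Points give the log2 value of each of 18 called genes in mice 1 to 4, with 1 called probe set per gene, horizontal lines the mean of the 4 mice, and the dotted line the mean background limit of 6.12. Pbsn stands at 6.57 in mouse 1 and at 3.02 to 3.47 in the others, and every immunoglobulin gene right of the dashed line is lowest in mouse 4.

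In all, 35 of 12422 probe sets were called at an adjusted p threshold of 0.05, of which 20 read a single gene (18 genes), and 15 did not. The median SD was 0.11, and 94 probe sets (0.757%) had a range over 1 log2 unit. At an unadjusted p under 0.05 stood 676 probe sets, or 5.44%. The prior was fitted to these same variances, so a share near the threshold is largely built in and does not show whether the mice differed. The count changed with the probe sets tested, the prior fit and the mice included. With the 3278 probe sets above the mean background limit alone 0 were called by limma (175 at an unadjusted p under 0.05, lowest adjusted p 0.198), and above the median signal 1 (Gas5). These filters changed the tested set, the prior and the adjustment at once. With a non-robust prior fit 15 were called, without mouse 2 23 and without mouse 4 17. Raising the SD of simulated probe sets 3-fold gave calls for 4.48% of them, 6-fold for 49.3% and 10-fold for 83.3%, so a gene that was not called may still have differed between the mice.

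Most fixed lists held no called gene. Beside Pbsn in the prostate list and the 3 immunoglobulin-related genes in the B and plasma cell list, 0 genes of the other 30 lists were called by limma's variance model over all probe sets, with 53 of their 616 genes at an unadjusted p under 0.05. Adjusted over the list alone, 3 heat shock and hypoxia genes passed, and so did 2 genes each of the smooth muscle, fibroblast, erythrocyte and immediate early lists and 1 each of the seminal vesicle secretion, interferon and secretory pathway lists. Among these, named after their values were seen, Cnn1 had 10.61 in mouse 1 against 9.73, 9.88 and 9.81, Mt2, a metallothionein gene, had 7.75, 6.79, 7.97 and 7.11, and Qsox1, a secreted sulfhydryl oxidase gene, had 10.47, 9.84, 10.60 and 9.66 in mice 1 to 4.

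The third question was whether the genes of a list moved together between the mice. Smooth muscle genes did: their mean deviation from each gene's own 4-mouse mean was 0.33 in mouse 1, -0.18 in mouse 2, -0.02 in mouse 3 and -0.13 in mouse 4, and all 12 genes above the limit were highest in mouse 1. Acta2 had 9.12 in mouse 1 against 8.57, 8.91 and 8.64, Myh11 had 9.80 against 9.58, 9.69 and 9.34, and Actg2 had 10.55 against 10.03, 9.91 and 10.18. The SD of the list over the mice was 0.229, against a median of 0.0424 for random lists of like signal (permutation p = 1e-04, the smallest that 10000 lists can give, adjusted 9e-04). Without mouse 1 the SD was 0.0820 (permutation test, adjusted p = 0.254). The 3' minus 5' difference of the beta-actin control put the mice in the same order as this list, at 1.08, 0.82, 1.02 and 0.98, while that of Gapdh did not, at -0.116, -0.147, -0.150 and -0.134. The fibroblast and matrix list was also highest in mouse 1, at 0.10 with 8 of its 15 genes highest there and 0 lowest. Whether RNA quality or the share of stroma accounts for the change was not tested.

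Genes of macrophages and dendritic cells also moved together, with -0.09, 0.09, 0.24 and -0.24 in mice 1 to 4. Of their 12 genes above the limit, 10 were highest in mouse 3 and 10 lowest in mouse 4. The macrophage markers Cd68, Adgre1 and Csf1r were under the limit and did not enter. Of the genes that did, named after their values were seen, the invariant chain gene Cd74 had 9.08, 9.47, 9.58 and 8.81, the MHC class II gene H2-Ab1 had 7.08, 7.27, 7.53 and 6.86, and the complement gene C1qa had 6.63, 6.70, 6.97 and 6.44. Cd74 and H2-Ab1 are also expressed by B cells. Immunoglobulin and J chain probe sets above the median signal were likewise most often highest in mouse 3 (13 of 30) and lowest in mouse 4 (22 of 30). Of 6 B cell surface genes 1 was above the limit, so they were too dim to set beside these. The SD was 0.209 against a random median of 0.0384 (permutation p = 1e-04, the smallest possible, adjusted 9e-04), and without mouse 3 it was 0.140 (permutation test, adjusted p = 0.0867).

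Heat shock and hypoxia genes deviated by 0.03, -0.16, 0.19 and -0.06 in mice 1 to 4 (SD 0.148 against a random median of 0.0433, 10 genes, permutation p = 0.0028, adjusted 0.0168), with 5 of 10 highest in mouse 3. The list's first genes did not carry this: the heat shock gene Hspa1b had 7.07, 6.89, 6.98 and 6.87, and Hspa8 had 7.19, 7.33, 7.36 and 7.58. The metallothionein gene Mt1, named after its values were seen, had 7.62, 7.05, 8.17 and 7.52. The call ended with each array shifted to the same median (SD 0.134, permutation test, adjusted p = 0.0558), with the list median in place of the mean (0.0901, adjusted permutation p = 0.0687), without mouse 2 (0.129, adjusted permutation p = 0.0792) and without mouse 3 (0.0911, adjusted permutation p = 0.189).

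The remaining 15 of 18 lists tested were not called. Seminal vesicle secretion had an SD of 0.0411, with deviations of 0.04, 0.01, 0.01 and -0.06 (permutation test, adjusted p = 0.676). Luminal epithelium, with Krt8 at 8.44, 8.50, 8.43 and 8.63 in mice 1 to 4, had an SD of 0.0890 (permutation test, adjusted p = 0.129), and fibroblast and matrix had 0.0702 (permutation test, adjusted p = 0.137). The number of lists called was 15 of 30 when dim genes were kept, 7 of them lists that the main test did not include, 5 of 18 with the list median and 1 of 17 without mouse 3. Genes are not replicates, so these tests describe the 4 arrays at hand.

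**Figure D3:**
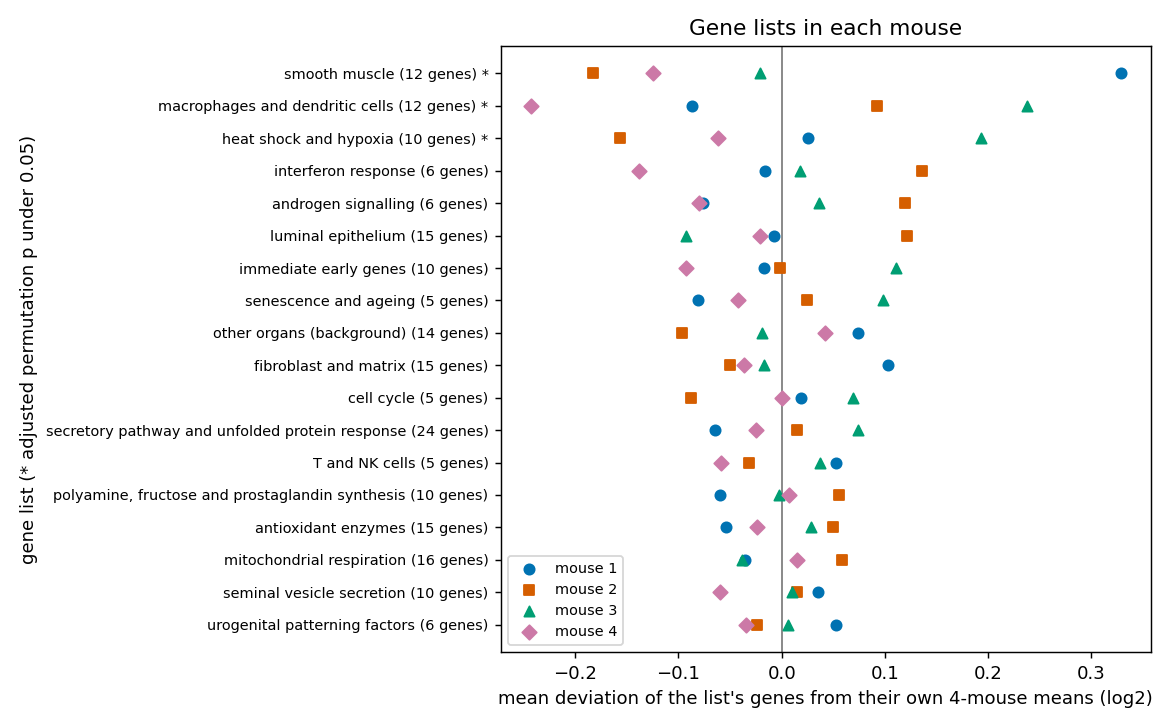
Points give the mean deviation (log2) of each list's genes from their own 4-mouse means in mice 1 to 4, for the 18 lists with at least 5 genes above the limit, ordered by SD. The smooth muscle list stands at 0.33 in mouse 1, and the macrophage and dendritic cell list spans -0.24 in mouse 4 to 0.24 in mouse 3.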

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

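The tests of explanations below were chosen after the results were seen. A sample was singled out when the gap of the highest or lowest mouse to the nearest other mouse, as a share of the range, exceeded Dixon's 95% critical value for 4 samples. This held for 7 results among 107 named probe sets and 18 lists, and chance gives about 1 in 20, as it did over all probe sets of the array, where 5.09% exceeded the value.

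Pbsn in mouse 1 had a gap share of 0.873 and lay 3.39 log2 units above the median of the other mice, whose values of 3.02 to 3.47 were all under the background limit, so both figures are uncertain. Probasin is made by prostate epithelium, which adjoins the seminal vesicle, so prostate tissue carried over into this sample may account for it. The other 11 prostate-list genes differed in mouse 1 by a median of 0.0503 from the median of the other 3 mice, and 3 of them, Mmp7 (0.44), Apof (0.28) and Pigr (0.34), were highest there. Msmb (-0.10) and Sbp (0.05), which are in the same list, did not rise with Pbsn. Only 3 of the 11 had a mean above the limit, and no prostate array shows how strongly the others read in prostate. The comparison therefore neither bears out nor excludes carry-over. A fault of the probe set stays open too, since 1 probe set reads Pbsn, and no biological explanation was tested.

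The other 6 results of this kind were small in size. Trp63 in mouse 3 had a gap share of 0.837 at a difference of -0.07 from the median of the others. Ccnb2 in mouse 3 had 0.891 (0.32), Col3a1 in mouse 4 had 0.913 (0.12), S100b in mouse 4 had 0.831 (0.18), Cdkn1a in mouse 3 had 0.842 (0.11) and Hoxa13 in mouse 2 had 0.922 (-0.08). None of these 6 genes was called by limma's variance model.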

How the results depend on the processing

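No paired analysis was possible because the labels give 1 group. Where a call or count changed, the cause was not tested unless the setting itself (fewer mice) shows it. The count of variable probe sets, 35 as reported, ranged from 17 (without mouse 4) to 44 when a mouse was left out (23 without mouse 2), and was 15 with a non-robust prior fit, 0 among probe sets above the mean background limit (where the prior had 4.74 degrees of freedom, against 8.06), 1 among those above the median signal and 8 at an adjusted p of 0.01; it stayed within 1.5 times under either rescaling and without a trend. The number of lists called, 3 of 18 tested, ranged from 1 of 17 (without mouse 3) to 4 of 19 (without mouse 4) when a mouse was left out, and was 15 of 30 with dim genes kept, where 7 of the called lists were not in the main test, and 5 of 18 with the list median. With 1 mouse left out, the SD of the smooth muscle list ranged from 0.0820 (without mouse 1) to 0.280, that of macrophages and dendritic cells from 0.140 (without mouse 3) to 0.247, and that of heat shock and hypoxia genes from 0.0911 (without mouse 3) to 0.181. The SD of heat shock and hypoxia genes was 0.134 with arrays shifted to the same median and 0.0901 with the list median, both no longer called. Probe sets above the background range numbered 5644 with the 75th percentile, 5834 with each array's median and 5870 with the highest Bacillus subtilis control, and from 2927 to 3047 with 1 mouse left out. The prostate list had 0 genes above at the 95th percentile. Of the named probe sets, 8 lost their call without mouse 4, 4 without mouse 1, 2 without mouse 2, 0 without mouse 3, 11 among probe sets above the median signal, 10 among those above the mean background limit, 9 with the mean of all probe sets of a gene, 8 at an adjusted p of 0.01, 5 with a non-robust prior fit, 3 with arrays shifted to the same median, 2 without a trend and 1 with quantile normalization. Dim signal limits what these arrays show, since 2917 of 12422 probe sets were above the background range.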

Other observations

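The tests of explanations in this part were chosen after the results were seen, except the first count of neighbouring genes, which was written before its result. Hba-a1 and Hbb-b2, which mark blood, had 7.88, 8.51, 7.71 and 8.39, and 4.19, 5.31, 4.30 and 4.65 in mice 1 to 4. Both were called when adjusted over the erythrocyte list alone and not over all probe sets.

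Of 67 immunoglobulin and J chain probe sets, the 30 above the median signal were examined. Over these, mouse 4 lay a median of -0.45 from the median of the others, 22 of 30 were lowest in it and 3 of 30 were highest. Array-wide or signal-dependent scaling is argued against, since the lowest of 10000 random lists of like signal reached -0.142. Cross-hybridisation between the families stays open: the 12 probe sets not marked by the maker as shared had a median of -0.150, with a 95% bootstrap interval of -1.27 to 3.25e-04, and 7 of them were lowest in mouse 4 while 2 were highest, among these a dimmer probe set of Ighm at 4.85, 4.67, 5.37 and 6.03 (adjusted p = 0.0849, limma). Of these 7, 1 reads Jchain, which lay at -1.35, belongs to no immunoglobulin family and would not be lowered by such cross-hybridisation alone. Its values in mice 1 and 4 were under the background limit, so the size of this difference is uncertain. A lower share of B-lineage cells may also account for it and stays open, as 6 B cell surface genes had a median of 0.0696 with 1 of 6 above the limit, and no group in the labels sets mouse 4 apart.

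A further pattern was noticed in the data and is a hypothesis only. Of 141 genes at an unadjusted p under 0.01 in limma's variance model, immunoglobulins left out, 82 ordered the mice with 1 and 3 on one side and 2 and 4 on the other, against 23 and 36 for the other splits, while 33.2% of all 8251 genes had this order. Segments of another strain's genome would place such genes side by side. Of 47 pairs within 5 Mb among all 141 genes, 8 had an absolute correlation over 0.9 (median of shuffles 9, 95th percentile 15, permutation p = 0.701). This count gave no excess of such pairs among the 141 genes as a whole. Its power was not checked, so segments are not excluded. Among the 82, pairs within 5 Mb numbered 24 whatever their correlation (95th percentile 30, permutation p = 0.261), which leaves segments open there too. A difference between single probe sets stays open as well, since only 2 called genes of the pattern had another probe set above the median signal. Neither of these followed by the rule used (Tubb2a r = -0.887 and SD 0.17, Gas5 r = 0.884 and SD 0.19), as that explanation predicts, but 2 genes are too few to decide. A different time of day of dissection is a candidate explanation, but no test of it decides. With 2 of 12 measured daily clock genes above the limit the test as first written could not be run. A second, with all 12 signed by their known phase and chosen after their values were seen, gave an SD of 0.116 over the mice. Random lists had a median of 0.0365 (permutation p = 0.0028). Of the 12, Dbp (unadjusted p = 0.0060, limma) and Nr1d2 (unadjusted p = 0.0011, limma) are themselves among the 82 genes, and random lists ignore co-regulation. The second test thus partly restates the pattern. The same split appeared in the beta-actin 3' minus 5' difference (1.08 and 1.02 against 0.82 and 0.98), though not in that of Gapdh (-0.116 and -0.150 against -0.147 and -0.134). Hba-a1 and Hbb-b2, given above, had it too. At unadjusted p of 0.0055 and 0.0012 (limma) they met the p limit and the order that define the pattern. They are therefore no separate sign of it. Of the 9 measured mast cell genes, 7 were higher in mice 1 and 3 and 1 was lower, with Tpsb2, named after its values were seen and the only one above the background range, at 8.06, 7.69, 8.05 and 7.81 in mice 1 to 4. In the heat shock and hypoxia list 11 of 19 were higher and 3 lower. In the smooth muscle list 10 of 17 were higher and 0 lower. These lists were picked after the counts of all lists were seen, from those with the largest shares of genes split this way. Some lists leaned the opposite way: of 20 luminal genes 1 was higher in mice 1 and 3 and 7 were lower. Of 24 mitochondrial respiration genes 2 were higher and 8 lower. At least Cma1, Smtn and the heat shock and hypoxia genes Mt1, Mt2 and Hsph1, from the picked lists, are themselves among the 82 genes. These counts therefore partly restate the pattern. RNA quality and the content of blood, mast cells or other cell types are further candidates and were not tested.

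In that clock list the split rested on part of the genes, most of them dim. Nr1d2 had 6.09, 6.99, 5.88 and 6.28 in mice 1 to 4, Nr1d1 had 5.55, 6.05, 5.53 and 5.87, Dbp had 4.19, 4.58, 3.71 and 4.48, and Tef had 7.82, 7.99, 7.79 and 7.92, all higher in mice 2 and 4. Of the 5 genes that peak in antiphase, Arntl alone went the opposite way, with 4.19, 3.71, 4.16 and 3.94. Per2, at 2.35, 2.41, 2.32 and 2.42, followed the split far under the background limit. In all, 6 of 12 genes split the mice this way, each in the direction of its phase, and Per1, Per3, Npas2, Clock, Nfil3 and Cry1 did not. None was called over all probe sets, and the labels give no time of dissection.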
